A study of Homo sapiens with 6 samples.

How the data were processed

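RNA-seq was analysed from 6 samples of PC-3, an established human prostate cancer cell line grown, per the labels, in medium with 10% fetal bovine serum. The samples formed 2 groups of 3, cells with a control short hairpin RNA (shControl) and cells with a short hairpin RNA against PHF8 (shPHF8). Per the labels' protocols, RNA was isolated with Trizol, its integrity number was above 8.0 on a Bioanalyzer, and mRNA libraries were made with standard Illumina protocols.

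The authors deposited 1 table of raw read counts per gene symbol, with 1 column for each of the 6 samples and no normalization. The values were whole numbers whose totals differed between samples. HISAT2 and the GRCh38 build are named in the submitters' processing notes. The read counter, the annotation release and the use of strand information were not given in the sources used here. Reads from overlapping or antisense genes therefore could not be told apart, and reads shared by near-identical gene copies may have been split or dropped. The table held 54256 gene symbols, of which 47820 matched a RefSeq symbol or a single synonym and 35443 matched a gene of GENCODE release 29. Coordinates, exon overlaps, transcript GC content and exon lengths were taken from GENCODE release 29 on GRCh38. Mitochondrial genes carried RefSeq-style names such as CYTB and COX3, and older symbols such as CTGF and ACPP were kept as given.

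Library totals ran from 17646347 to 22404624 counts. At these depths 3 counts in 1 library equalled 0.134 to 0.170 CPM, the counts scaled to the library total, and this floor covers counting error only. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15357 symbols holding 99.9% of the counts of each library. Libraries were scaled with TMM factors, and CPM values are on that scale. The comparison used edgeR's quasi-likelihood test (estimateDisp, glmQLFit and glmQLFTest, with group as the only term) with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The common biological coefficient of variation was 0.0933. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic, and 95% confidence intervals used its total degrees of freedom. Adjusted p-values of genes in the results are from this test.

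The 18 gene lists, the rule for named genes, the tests and the first set of alternatives were fixed before the data were examined. The lists covered E2F and DNA replication, mitosis, mesenchymal, epithelial and TGF-beta response genes, histone demethylases, ribosome biogenesis, hypoxia, interferon-stimulated, NF-kappaB and cytokine, p53 and growth arrest, unfolded protein and amino acid stress, cholesterol and fatty acid synthesis, luminal prostate, neuroendocrine, leukocyte, endothelial and erythroid, cytosolic ribosomal protein, and mitochondrially encoded genes. They held 535 memberships, of which 464 were tested, and 1 listed gene was not matched in the table. Each list was tested against all other tested genes with limma's camera on log2 CPM (prior count 3, preset inter-gene correlation 0.01), adjusted over the 18 lists. Adjusted p-values of lists in the results are from this camera test unless another setting is named. Counts of members past the threshold are given over all tested genes and adjusted over the list alone. The genes named were PHF8, E2F1 and SNAI1, then the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups. The 3 members with the smallest adjusted p in each list completed the rule, and 1 gene that it names is not reported here. Other members of the lists, and all genes of the closing section outside the rule, were chosen after their values were seen.

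The gene test and the list test were tested on simulated counts drawn for the 15357 tested genes of this comparison with 200 genes changed. The test called 74.0% of 50 genes changed 1.5-fold, 88.0% of 50 changed 2-fold, 94.0% of 50 changed 3-fold and 96.0% of 50 changed 4-fold, and called 0 unchanged genes. Camera called 0 of 18 simulated lists without a change and called a list of 30 genes raised 1.3-fold. The simulated genes were drawn independently of each other, so lists with correlated members were not tested and the preset correlation was not checked. The simulation also changed 200 genes, far fewer than the 6145 called in the data. The spread between simulated samples depended on expression level alone. Replicates 1 and 2 were not drawn closer to each other, and replicate 3 carried no shift with GC content or exon length. The 0 false calls therefore do not show how many false calls the data hold.

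The alternatives were RLE factors, upper-quartile factors, library totals only, DESeq2, limma voom, no filter on low counts, a filter of at least 1 CPM in 3 samples, leaving out each sample, the replicate number as a block, and a robust quasi-likelihood fit. Lists were also tested with an estimated inter-gene correlation and with fry. Offsets corrected for GC content, and a fit with replicates 1 and 2 of each group summed, were added after the data were seen. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.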

Results

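Gene expression was measured by RNA-seq in PC-3 cells, a human prostate cancer line derived from a bone metastasis, with either a control short hairpin RNA (shControl, 3 samples) or a short hairpin RNA against PHF8 (shPHF8, 3 samples). PHF8 is a JmjC-domain histone demethylase, and the study's title connects it to metastasis through E2F1 and SNAI1. The comparison asked which transcripts differ when PHF8 is lowered. The shControl libraries held 22404624, 20192820 and 20313700 counts and the shPHF8 libraries 18407241, 17646347 and 21520687, and 15357 genes were tested. Within each group, replicates 1 and 2 were much closer to each other (chi-square per gene 2.10 in shControl and 2.39 in shPHF8) than either was to replicate 3 (12.4 to 19.7). All pairs differed by more than sampling noise and were counted as separate samples. The labels do not say whether samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The library of shPHF8 replicate 3 also differed from replicates 1 and 2 of its group along transcript GC content, with a Spearman correlation of 0.56 across 13828 genes, which are not independent replicates. Its correlation with exon length was -0.18. For shControl replicate 3 against replicates 1 and 2 of its group, the correlation was 0.19 with GC content and -0.43 with exon length. The log2 fold changes between the groups correlated with GC content at 0.24, and at 0.16 from replicates 1 and 2 alone.

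PHF8 mRNA fell to 47.0% of its control level, from 37.9 ± 4.26 CPM in shControl to 17.8 ± 1.07 CPM in shPHF8 (SD, n = 3 each; log2 fold change -1.09, SE 0.10; edgeR adjusted p = 1.34e-05). Its counts were 891, 816 and 663 in the shControl libraries and 331, 298 and 407 in the shPHF8 libraries, so each library matched its label. E2F1, the transcription factor that drives entry into DNA replication, fell to 51.8% of control, from 78.5 ± 9.72 to 40.6 ± 6.34 CPM (SD, n = 3 each; log2 fold change -0.95, SE 0.12; edgeR adjusted p = 1.04e-04). SNAI1, a repressor of E-cadherin transcription, was weakly expressed at 1.47 ± 0.496 CPM in shControl and 1.80 ± 0.211 CPM in shPHF8. Its difference did not pass the test (log2 fold change 0.30, SE 0.28, 95% interval -0.32 to 0.91; edgeR adjusted p = 0.433), and its counts were 26, 24 and 41 against 30, 36 and 38. A two-sided exact permutation test of 3 against 3 samples gave p = 0.1 for PHF8 and E2F1, the smallest it can give, and p = 0.4 for SNAI1. In GRCh38 coordinates of GENCODE release 29, PHF8 lies on chromosome X from 53936676 to 54048958 on the minus strand. E2F1 lies on chromosome 20 from 33675683 to 33686404 on the minus strand, and SNAI1 on chromosome 20 from 49982999 to 49988886 on the plus strand.

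**Figure D1:**
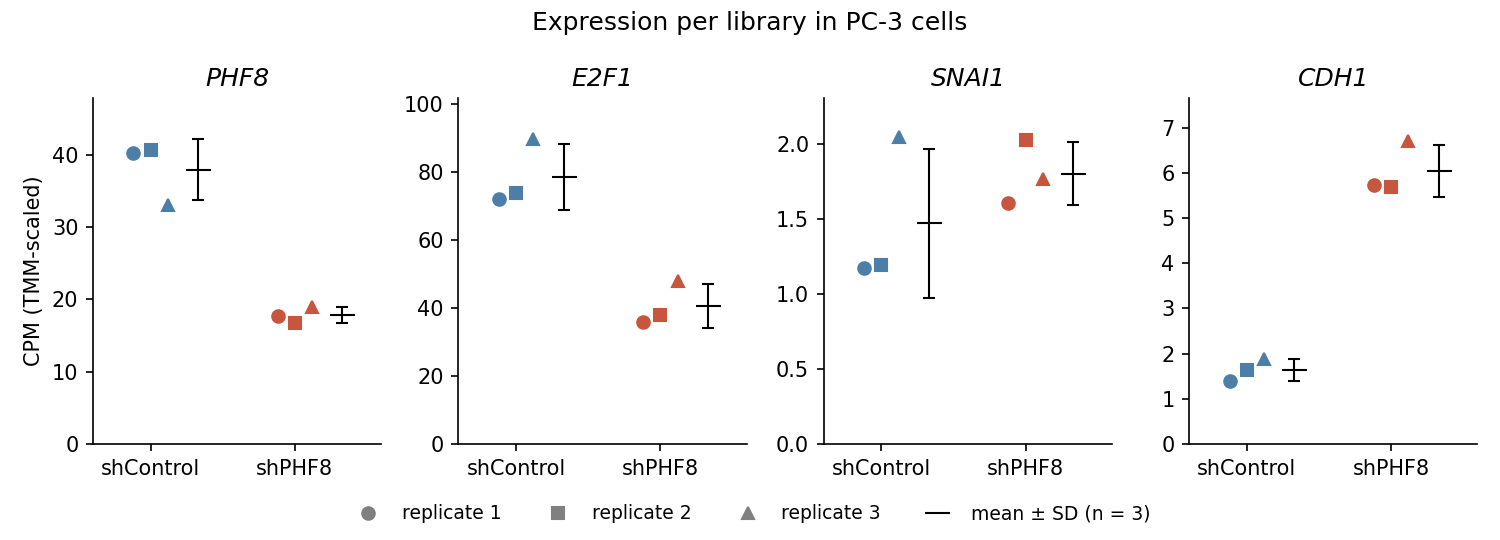
TMM-scaled CPM of PHF8, E2F1, SNAI1 and CDH1 in each library (y axis, linear from 0), with blue points for shControl, red points for shPHF8, marker shapes for the replicate numbers, and bars for mean ± SD (n = 3). The groups are apart for PHF8, E2F1 and CDH1, whereas for SNAI1 the highest shControl library (2.04 CPM) reaches the highest shPHF8 library (2.03 CPM).

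TSPAN8, a tetraspanin of the cell surface, rose from 14.8 ± 0.290 to 267 ± 14.0 CPM (SD, n = 3 each), an 18.05-fold rise. SDC1, which encodes the heparan sulfate proteoglycan syndecan, fell from 1202 ± 20.5 to 289 ± 29.05 CPM, 4.17-fold lower (SD, n = 3 each). In all, edgeR called 6145 genes (40.0% of those tested), 3177 higher and 2968 lower in shPHF8, and 753 of the higher and 339 of the lower genes changed by at least 1 on the log2 scale. No overlap between the groups was seen in 52.3% of tested genes, where chance gives 10% if all libraries are independent of each other. Within each group some libraries were much closer to each other than to the rest. The share given by chance may therefore be higher, by an amount that was not tested. The other large rises among genes at 5 CPM or more were CP, the copper-carrying ferroxidase ceruloplasmin (62.6-fold), the bicarbonate cotransporter SLC4A4 (20.9-fold), the secreted lectin REG4 (12.4-fold) and the type III collagen gene COL3A1 (10.0-fold). The chemokines CXCL10 (17.3-fold) and CXCL11 (10.4-fold) also rose. CP had only 8, 3 and 1 counts in the shControl libraries, shares 19.4% of its exon length with genes on the other strand, and had a log2 fold change of 6.87 without shControl replicate 1 against 5.97 with it. RPPH1, the RNA subunit of RNase P, was 14.97-fold higher but at 13.6 ± 14.3 CPM in shPHF8 (SD, n = 3). RPPH1 shares all 333 bases of its exon length with another gene on the same strand. Its log2 fold change was 2.59 without shPHF8 replicate 3 against 3.90 with it, and its call was lost in the robust edgeR fit (adjusted p = 0.0712). The other large falls were the dehydrogenase gene DHRS2 (9.65-fold lower, from 95.8 ± 2.84 to 9.95 ± 1.21 CPM; SD, n = 3 each), the kinase PAK3 (9.15-fold lower), the transgelin family member TAGLN3 (4.99-fold lower) and the non-coding RNA LINC00659 (4.31-fold lower). GSDMD, the pore-forming effector of pyroptosis (4.06-fold lower), the EGF-family ligand EPGN (4.01-fold lower) and LOC102724548 (3.82-fold lower) completed this group. The largest edgeR adjusted p among these 16 genes was that of RPPH1, at 0.00217, followed by GSDMD at 5.64e-04.

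**Figure D2:**
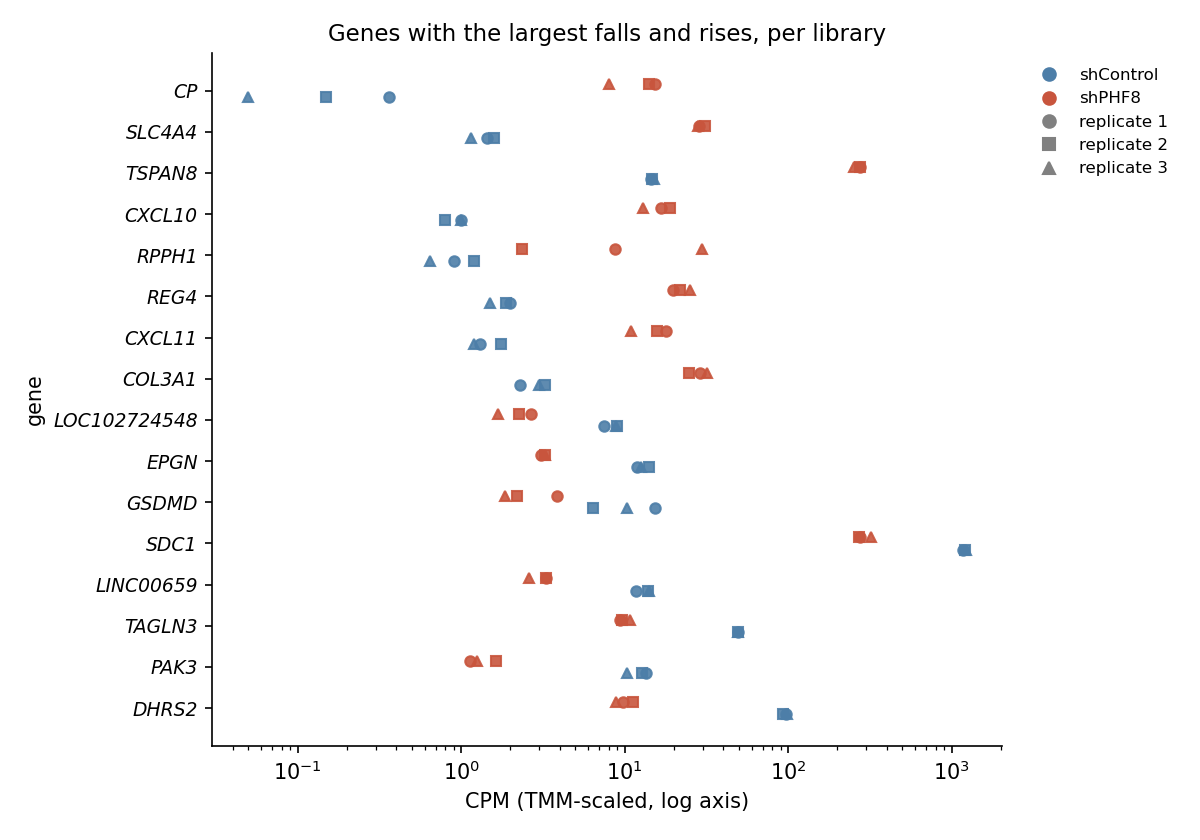
TMM-scaled CPM per library (x axis, log scale) of the 8 genes with the largest rises and the 8 with the largest falls (y axis), with blue points for shControl, red points for shPHF8 and marker shapes for the replicate numbers. The libraries of both groups are apart for each gene because the rule that chose these genes required it. On this log scale the shPHF8 libraries of RPPH1 spread most widely, at 13.6 ± 14.3 CPM (SD, n = 3).

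Genes of DNA replication fell together with E2F1. Of 39 tested E2F and DNA replication genes, 36 were lower in shPHF8 and 0 higher, with a median log2 fold change of -0.75 (camera adjusted p = 4.86e-17, and adjusted p = 0.0395 with an estimated correlation). Adjusted over the list alone, 36 were lower as well. CDC6, which loads the replicative helicase, fell from 73.3 ± 1.05 to 27.6 ± 1.54 CPM (SD, n = 3 each; log2 fold change -1.41, SE 0.08). The cohesion factor DSCC1 (2.42-fold lower) and UHRF1, which couples DNA methylation to replication (2.22-fold lower), followed. The helicase subunits MCM2 to MCM7 all fell, with log2 fold changes from -1.06 for MCM5 to -0.50 for MCM3. POLE (-0.16), CCNE1 (0.04) and E2F7 (0.10) did not pass. Mitotic and G2/M genes were lower by a smaller margin, 32 of 35 with 0 higher and a median log2 fold change of -0.49 (camera adjusted p = 1.02e-09, but adjusted p = 0.105 with an estimated correlation). Adjusted over the list alone, 32 were lower. The kinesin KIF4A (1.42-fold lower), the phosphatase CDC25C (1.45-fold lower) and the anaphase activator CDC20 (1.46-fold lower) had the smallest adjusted p of this list. Without shPHF8 replicate 3, 36 E2F and 32 mitotic genes were lower.

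Interferon-stimulated genes rose broadly. Of 39 tested, 33 were higher in shPHF8 and 0 lower, or 37 and 0 adjusted over the list alone, and the median member was 2.23-fold higher (camera adjusted p = 4.86e-17, and adjusted p = 0.0345 with an estimated correlation). OASL, an oligoadenylate synthetase-like antiviral protein, rose from 47.1 ± 0.533 to 228 ± 21.99 CPM, IFIT3 from 49.8 ± 2.94 to 208 ± 15.3 CPM and OAS2 from 29.7 ± 1.86 to 92.9 ± 2.12 CPM (SD, n = 3 each). The double-stranded RNA sensors IFIH1 (log2 fold change 2.27) and OAS1 (1.16) rose as well, whereas MX2 (-0.36) did not pass. Without shPHF8 replicate 3, 37 of the list were higher and 0 lower. NF-kappaB and cytokine genes moved both ways, 13 of 24 higher and 5 lower, or 14 and 5 adjusted over the list alone, with a median log2 fold change of 0.44 (camera adjusted p = 0.0108, but adjusted p = 0.230 with an estimated correlation). The pathway inhibitor NFKBIA rose 2.65-fold and the mitochondrial superoxide dismutase SOD2 rose 2.01-fold. BCL2A1, an anti-apoptotic BCL2 relative, was 3.38-fold lower (44.5 ± 3.12 to 13.2 ± 1.89 CPM; SD, n = 3 each). IL6 rose (log2 fold change 2.26). The neutrophil chemokine genes went both ways, since CXCL8 (-0.89), CXCL1 (-0.67) and CXCL5 (-1.01) fell, CXCL6 rose (0.95), and CXCL2 (0.22) and CXCL3 (0.06) did not pass.

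**Figure D3:**
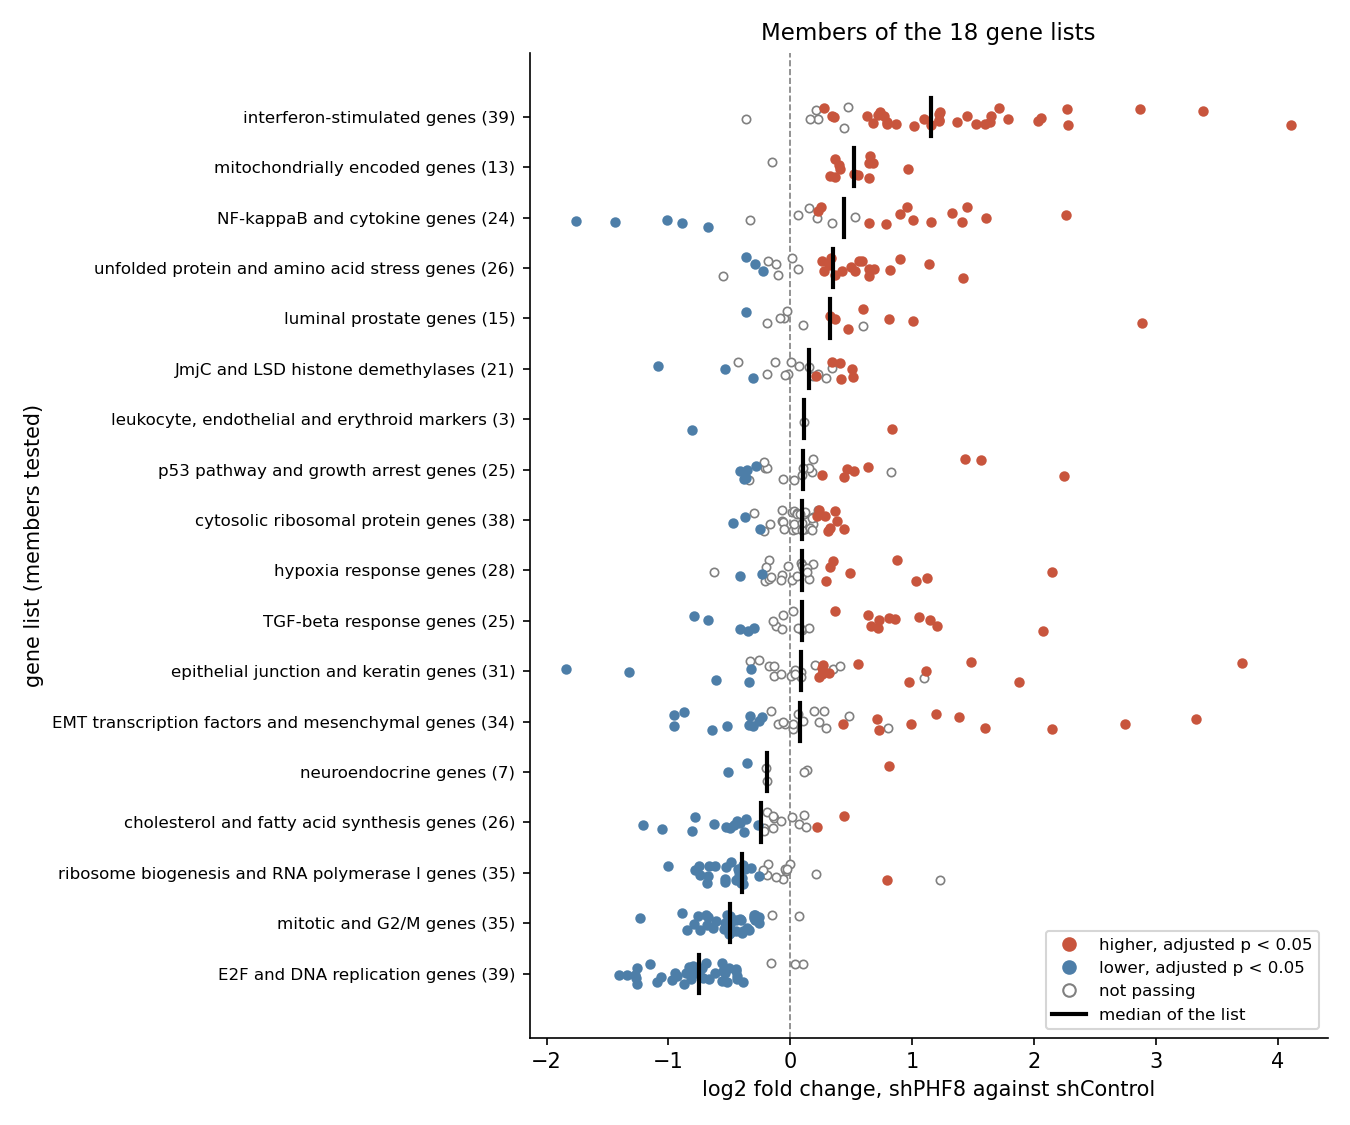
Log2 fold change of shPHF8 against shControl (x axis) for the tested members of the 18 gene lists (y axis, with the number tested), where red and blue points passed adjusted p below 0.05, open points did not, and black bars mark each list's median over all tested members, 1 of which, a luminal prostate gene, is not drawn. The E2F and DNA replication list has its median at -0.75 and the interferon-stimulated list at 1.16.

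Neither the mesenchymal nor the epithelial list passed camera's test, although single members changed strongly. Of 34 EMT transcription factors and mesenchymal genes, 10 were higher and 10 lower, or 11 and 10 adjusted over the list alone (median log2 fold change 0.08; camera adjusted p = 0.249). The matrix proteins SPARC (24.96 ± 1.31 to 167 ± 11.9 CPM; SD, n = 3 each) and COL3A1 and the collagen cross-linking enzyme LOX (4.42-fold) rose. The transcription factors ZEB1 (log2 fold change -0.52) and SNAI2 (-0.64) and the intermediate filament gene VIM (-0.25) fell. Of 31 epithelial junction and keratin genes, 11 were higher and 5 lower, or 13 and 5 adjusted over the list alone (median 0.09; camera adjusted p = 0.249). CDH1, the E-cadherin gene, rose 3.68-fold from a low level (1.64 ± 0.248 to 6.04 ± 0.568 CPM; SD, n = 3 each), the desmosomal linker PPL rose 1.96-fold, and the epithelial transcription factor EHF rose 13.1-fold from 5, 2 and 3 counts in the shControl libraries. LSR (log2 fold change -1.84) and KRT7 (-1.32) fell. Of 25 TGF-beta response genes, 11 were higher and 5 lower, both over all genes and adjusted over the list alone (median 0.09; camera adjusted p = 0.0848). BAMBI, a decoy receptor that dampens TGF-beta signalling, rose 4.20-fold, CTGF rose 2.21-fold and JUNB rose 2.30-fold. JUNB shares 14.2% of its exon length with genes on the other strand.

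Of 35 ribosome biogenesis and RNA polymerase I genes, 23 were lower and 1 higher, the same counts as adjusted over the list alone (median log2 fold change -0.39; camera adjusted p = 1.42e-06, and adjusted p = 0.0367 with an estimated correlation). The nucleolar proteins NOLC1 (to 49.9% of control) and NCL (1028 ± 28.1 to 641 ± 38.6 CPM; SD, n = 3 each) and the pre-rRNA processing factor WDR43 (1.72-fold lower) fell. Of 26 cholesterol and fatty acid synthesis genes, 13 were lower and 2 higher, also adjusted over the list alone (median -0.24; camera adjusted p = 4.38e-04, but adjusted p = 0.226 with an estimated correlation). INSIG1, which retains the sterol-sensing complex in the endoplasmic reticulum, fell 2.31-fold. The sterol carrier STARD4 (2.07-fold lower) and the isomerase IDI1 (1.72-fold lower) fell as well, and IDI1 shares 14.8% of its exon length with genes on the other strand. Of 26 unfolded protein and amino acid stress genes, 17 were higher and 3 lower, or 17 and 4 adjusted over the list alone (median 0.35; camera adjusted p = 0.00164, but adjusted p = 0.518 with an estimated correlation). ATF3 (2.67-fold), the glutathione-degrading enzyme CHAC1 (2.20-fold) and TRIB3 (1.87-fold) rose, while the chaperone HSPA5 stood at a log2 fold change of 0.01 that did not pass. Of 28 hypoxia response genes, 8 were higher and 2 lower, or 7 and 2 adjusted over the list alone (median 0.10; camera adjusted p = 0.249). STC2 (2.17-fold), DDIT4 (2.05-fold) and LOX rose, and DDIT4 shares 41.2% of its exon length with genes on the other strand. Of 25 p53 pathway and growth arrest genes, 8 were higher and 5 lower, or 8 and 6 adjusted over the list alone (median 0.11; camera adjusted p = 0.277). The stress cytokine GDF15 (4.76-fold), TP53INP1 (2.96-fold) and the CDK inhibitor gene CDKN2B (1.38-fold) rose.

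The luminal pioneer factor FOXA1 rose 2.01-fold (49.7 ± 1.51 to 99.8 ± 5.61 CPM; SD, n = 3 each), and the prostatic acid phosphatase gene ACPP rose from 0.424 ± 0.245 to 3.13 ± 0.349 CPM (SD, n = 3 each). Of 15 luminal prostate genes, 7 were higher and 2 lower, also adjusted over the list alone (median log2 fold change 0.32; camera adjusted p = 0.179). Of 7 tested neuroendocrine genes, 1 was higher and 2 lower, also adjusted over the list alone (median -0.19; camera adjusted p = 0.376). The histone methyltransferase EZH2 (1.42-fold lower) and FOXA2 (1.28-fold lower) fell, and the synaptic vesicle gene SYP was 1.75-fold higher at a low level of 1.23 ± 0.301 against 2.16 ± 0.171 CPM (SD, n = 3 each; edgeR adjusted p = 0.0256). The SYP call was lost with DESeq2 (adjusted p = 0.0546), with replicates 1 and 2 of each group summed (edgeR adjusted p = 0.0613), and without shControl replicate 2 or 3 or shPHF8 replicate 1 or 2 (edgeR adjusted p up to 0.0760). Among 21 histone demethylases, PHF8 included, 6 were higher and 3 lower, also adjusted over the list alone (median 0.15; camera adjusted p = 0.396). KDM4B rose 1.43-fold and KDM6B 1.42-fold, and the PHF8 relative PHF2 also rose (log2 fold change 0.42). KDM7A, the other close relative, stood at 0.30 and did not pass.

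Transcripts of the mitochondrial genome were higher in shPHF8, taking 4.15% ± 0.432 of counts against 3.01% ± 0.0859 in shControl (SD, n = 3 each). Of 13 mitochondrially encoded genes, 12 were higher and 0 lower, also adjusted over the list alone (median log2 fold change 0.53; camera adjusted p = 4.38e-04, but adjusted p = 0.518 with an estimated correlation). CYTB rose by a log2 fold change of 0.68, COX3 by 0.64 and ND1 by 0.56, and these genes have near-identical copies in the nuclear genome. Of 38 cytosolic ribosomal protein genes, 8 were higher and 3 lower, or 6 and 3 adjusted over the list alone (median 0.10; camera adjusted p = 0.249). RPL32 (1.35-fold) and RPL37 (1.31-fold) rose and RPL14 (1.39-fold lower) fell. The list passed only without shControl replicate 3 (camera adjusted p = 0.0119), and ribosomal protein genes have many near-identical pseudogenes. Of 21 leukocyte, endothelial and erythroid markers, 3 had enough counts to be tested, 1 higher and 1 lower, also adjusted over the list alone (median 0.11; camera adjusted p = 0.894). The endothelial receptor gene KDR rose 1.78-fold (21.1 ± 2.18 to 37.5 ± 1.45 CPM; SD, n = 3 each), the lysosomal gene CD68 fell (1.75-fold lower), and PECAM1 stood at a log2 fold change of 0.11 that did not pass. The leukocyte gene PTPRC had 1 count in the shControl libraries together and 5 in the shPHF8 libraries.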

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

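Offsets corrected for GC content and the fit with replicates 1 and 2 of each group summed were chosen after the data were seen; the other alternatives were fixed before. The number of genes called by edgeR (6145) ranged from 4222 with replicates 1 and 2 summed to 6623 with no filter on low counts, DESeq2 called 5682 and limma voom 6166, and 0 genes were called in the opposite direction in any of these fits. Upper-quartile factors gave 3477 higher and 2660 lower genes. Leaving out 1 sample gave 4769 to 6394 calls. PHF8 ranged from -1.18 to -1.04 and E2F1 from -1.09 to -0.85 over all alternatives and both stayed past the threshold, while SNAI1 ranged from 0.15 to 0.60 with adjusted p from 0.112 to 0.757. Deviations of samples with the same replicate number correlated at 0.0047, 0.061 and 0.105. A sample numbered 1 or 2 did not always correlate best with its own number, so the numbers were not taken to pair the samples. The samples numbered 3 did correlate best with each other, and each stood apart from replicates 1 and 2 of its group. A difference shared by the samples numbered 3 therefore stays open. The replicate block gave 6299 calls, 3217 higher and 3082 lower. Of the 8 lists called by camera, 3 held with an estimated correlation. The adjusted p became 0.105 for mitotic, 0.230 for NF-kappaB and cytokine, 0.518 for unfolded protein and amino acid stress, 0.226 for cholesterol and fatty acid synthesis and 0.518 for mitochondrially encoded genes, while over the 9 other camera settings it was at most 3.99e-09, 0.0202, 0.00709, 0.00219 and 0.00119 for these lists in turn. Fry, which tests whether a list moves one way without comparing it with other genes, called lists that camera did not. Its adjusted p was 0.00122 for EMT and mesenchymal, 0.0201 for epithelial, 8.55e-04 for TGF-beta response, 0.00121 for hypoxia, 0.00240 for p53, 8.55e-04 for luminal prostate and 0.0208 for neuroendocrine genes. Without single samples, camera's adjusted p ranged from 0.0119 (without shControl replicate 3) to 0.717 for cytosolic ribosomal protein genes. It ranged from 0.657 to 0.992 for leukocyte, endothelial and erythroid markers, whose uncalled direction turned without shPHF8 replicate 2 (0.992) or 3 (0.915). PECAM1, not called, ranged from -0.011 without shPHF8 replicate 2 to 0.25. Among named genes, calls were lost for RPPH1 in the robust fit (adjusted p = 0.0712, the highest of its alternatives, the lowest being 7.45e-86), for RPL37 with replicates 1 and 2 summed (0.0515, at most 0.0152 without single samples) and for SYP in 6 settings (0.0199 to 0.0760 over all). For all of these shifts the cause was not tested. At library totals of 17646347 to 22404624 counts, low genes such as SNAI1, at 24 to 41 counts, limited what could be detected.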

Other observations

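The test of the shRNA response was chosen after the result was seen, as were all genes named here outside the named-gene rule and the symbol-family search; the other tests were written before their results were seen. Histone genes were higher in shPHF8. Of 253 families of symbols sharing a prefix with at least 8 tested genes, 4 held more higher genes and 9 more lower genes than the tested background. The strongest was HIST, with 25 of 34 genes higher, 1 lower and a median log2 fold change of 1.42 (Fisher's exact test, adjusted p = 2.66e-08 over both directions). This test counts the genes of a family as independent, although members may change together or share reads. Its p-values for all families given here may therefore be too small. HIST2H2BE rose from 11.5 ± 0.3002 to 73.96 ± 3.68 CPM, HIST1H2AC from 25.1 ± 1.57 to 89.5 ± 7.03 CPM and HIST1H1C from 45.3 ± 4.83 to 128 ± 13.1 CPM (SD, n = 3 each). HIST2H2AC was the 1 lower gene, at a log2 fold change of -0.99. Many histone genes are near-identical copies, so reads may have been split among them. Without shPHF8 replicate 3, 24 HIST genes were higher and 1 lower.

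All 8 HAUS genes, which encode the augmin complex of the spindle, fell, as did 19 of 36 CEP genes, many of which encode centrosome proteins (adjusted p = 4.89e-04 and 9.36e-04, Fisher's exact test). So did 7 of 9 PSMC and 11 of 18 PSMD genes, many of which encode parts of the proteasome's regulatory particle. Also lower were 7 of 10 CCT genes, most of which encode chaperonin subunits (Fisher's exact test, adjusted p = 0.0158, 0.00960 and 0.0269 for PSMC, PSMD and CCT). Families were set by symbol prefix alone and may hold other genes. PSMC4 did not pass (log2 fold change -0.78, edgeR adjusted p = 0.172). Its level was low, at 4.24 ± 2.27 CPM in shControl and 2.46 ± 1.27 CPM in shPHF8 (SD, n = 3 each). The proteasome core families did not pass, with 6 of 9 PSMA genes lower (adjusted p = 0.0714) and 1 of 8 PSMB genes lower (adjusted p = 1). With the trend with GC content removed, 7 HAUS, 17 CEP, 7 PSMC, 12 PSMD and 7 CCT genes were lower. CCT2 fell from 279 ± 12.1 to 165 ± 9.80 CPM. Outside these families, the HSPA chaperone genes did not pass as a family, with 7 of 12 lower and 2 higher (adjusted p = 0.0802), and neither did DNAJB (1 of 10 lower) or DNAJC (7 of 29 lower). Single genes of protein folding that fell included HSP90AA1, from 2945 ± 121 to 1491 ± 331 CPM, and BAG3, from 354 ± 13.6 to 202 ± 16.7 CPM (SD, n = 3 each), while HSF1, the transcription factor of the heat shock response, stood at a log2 fold change of -0.0024 that did not pass. Beside the listed interferon-stimulated genes, IFNB1, which encodes interferon beta, rose from 0.903 ± 0.210 to 7.13 ± 0.352 CPM and the lambda interferon gene IFNL1 from 0.250 ± 0.174 to 0.985 ± 0.272 CPM. GBP4 rose from 4.97 ± 1.03 to 27.98 ± 0.193 CPM and the RNA sensor TLR3 from 1.095 ± 0.132 to 2.32 ± 0.318 CPM (SD, n = 3 each). Among the single genes of this paragraph that passed, IFNL1 had the largest edgeR adjusted p, at 0.00770.

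The real grouping called 6145 genes, and the highest of the other 9 splits of the 6 samples called 0. Each of those 9 splits mixed shControl and shPHF8 samples in both arms, so the difference between the groups widened the spread within arms. Few calls were therefore likely there in advance, and no conclusion is drawn from them. The 10 splits are too few for a share under 0.05, since the real one alone is 1 of them.

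Interferon-stimulated genes were higher in shPHF8. Removing the trend with GC content from each library left 33 of the 33 called members called, and leaving out shPHF8 replicate 3 also left 33 of 33. The GC trend was small, with median log2 fold changes from -0.19 to 0.093 between the lowest and highest of 5 GC groups of genes. The first count could therefore hardly change. The list median, 1.11 with the trend removed and 1.16 with it, could hardly move for the same reason. It is the size of the trend, small beside this median, that argues against GC content as the whole cause. The second count was also likely in advance, since 6064 of the 6145 called genes showed no overlap between the groups. It shows only that the rise was also present in the other shPHF8 libraries. A response to the short hairpin RNA or its vector may also raise these genes, and the rise in IFNB1 and IFNL1 would be consistent with either that or a response to lower PHF8. The labels name 1 knockdown arm, so a response to the shRNA or its vector cannot be told apart from one to PHF8. A second, unrelated hairpin would be needed to separate them.

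E2F and mitotic genes were lower in shPHF8, the E2F list with adjusted p = 0.0395 with an estimated correlation, while the mitotic list did not pass there (adjusted p = 0.105 with an estimated correlation). With the trend with GC content removed, 36 of 36 called E2F genes and 32 of 32 called mitotic genes stayed lower, and the same counts, 36 and 32, were reached without shPHF8 replicate 3. The GC trend was too small to change these counts much. The list medians were -0.77 for E2F and -0.42 for mitotic genes with the trend removed, beside -0.75 and -0.49 with it. The medians of the 5 GC groups, from -0.19 to 0.093, were small beside these list medians, so GC content does not account for the falls as a whole. The counts without shPHF8 replicate 3 were likely in advance, since 6064 of the 6145 called genes showed no overlap between the groups. They show only that the falls were also present in shPHF8 replicates 1 and 2. A hypothesis is that slower entry into DNA replication, with E2F1 at 51.8% of its control level, may lie behind the falls. Cell cycle distribution was not measured here, and the same hairpin confound stays open.

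Histone genes were higher in shPHF8, although most replication-dependent histone mRNAs lack a poly(A) tail and go with DNA replication, whose genes were lower. More RNA without a poly(A) tail in the shPHF8 libraries might have raised them. In its favour, RPPH1 (14.97-fold), RN7SK (5.64-fold) and RMRP (5.92-fold), which also lack the tail, were called higher. Their median was 1.27 on the log2 scale in shPHF8 replicate 2, beside 1.31 for the histone genes. In that library RPPH1 (2.36 CPM) and RN7SK (9.35 CPM) stood above every shControl library, but RMRP did not, at 1.35 CPM against 1.29 to 1.40 CPM. Those RNAs differed between shPHF8 replicates 3 and 2 by a median of 3.57, however, and the histone genes by 0.0206, a ratio of 0.00578, which argues against a shared source for the whole rise and leaves a part of it open. With the trend with GC content removed, 24 of 25 called genes stayed higher, though that trend was small beside the histone median of 1.42. Polyadenylated histone transcripts, which could rise when cells leave the cycle, remain a hypothesis that gene counts cannot test.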
